A study of Caenorhabditis elegans with 2 samples.

How the data were processed

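Binding of UNC-62 was profiled by ChIP-seq, the sequencing of DNA recovered with a tagged protein, in whole L1 larvae of Caenorhabditis elegans. Per the labels, the animals carried a transgene of unc-62 fused to GFP together with unc-119 as a rescue gene, and 2 biological replicates formed the only group, UNC-62 L1. The labels gave a library size range of 150 to 350 bp. Control libraries were not analysed here.

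The peak lists were used as deposited, in builds ce11 and ce10. For each build there was 1 list per replicate, 1 list called on the pooled replicates, and 1 list thresholded by the irreproducible discovery rate (IDR), which compares the ranks of peaks between replicates. The deposited signal value of each entry is the authors' own measure of enrichment, and it was used only to rank, filter and describe entries. The deposited lists also gave a −log10 q-value per entry, in which many entries were tied at the highest value. The aligner, the peak caller and the IDR cutoff were not given in the sources used here. The lists held no read counts, so the depth of each library is unknown, and a difference in depth between replicates would change how much each contributed to the pooled list.

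All replicate and pooled lists held 30000 entries of fixed width, 336 bp in the pooled and replicate 2 lists and 370 bp in the replicate 1 list of ce11. A list of fixed length includes weak entries, so presence in it is not evidence of binding. The 119 IDR intervals were the 119 pooled entries with the highest signal. An IDR peak therefore need not have ranked alike in both replicates, and 7 had no entry in the replicate 1 list. Summits were the middle of each interval. Coordinates are 1-based in ce11, whose sequence is WBcel235, and genes came from Ensembl release 115. No coordinates were converted between builds.

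Gene 5′ ends were the ends of the 19973 annotated protein-coding gene records, so internal starts of shorter transcripts were not counted. Features at summits were also those of protein-coding genes, so sequence called intergenic may hold non-coding genes. IDR peaks were compared with the 29865 pooled entries that met no IDR peak, by 2-sided Fisher exact tests. Motifs were searched on both strands within 100 bp of the summit, against up to 10 entries per peak matched on GC decile and on lying within 1 kb of a 5′ end. Gene lists were compared over the 9799 genes with a pooled entry within 1 kb. P-values were adjusted by the Benjamini-Hochberg method over 8 motifs or 23 lists, with a threshold of 0.05. The replicate overlap was compared with 1000 random draws. Intervals are exact 95% binomial intervals and cover counting error only. Peaks and genes are not biological replicates, so these tests describe the lists and not the spread between animals.

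The tests, motifs, gene lists and alternatives were fixed before the data were examined, apart from those identified as chosen later. The text names the genes nearest to the 20 strongest IDR peaks, genes that share or contain these summits, members of lists of up to 40 genes near an IDR summit, the 3 strongest members of longer lists, and the transgene loci. Genes named outside that rule are identified as chosen after their values were seen. Names of 5 heterochronic genes and 1 intestine marker were not matched in the annotation and were left out.

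The functions were tested on simulated data. A hexamer planted in 40 of 119 windows was found in all 40, and 2 of 100 draws with none planted gave a Fisher exact p under 0.05. A simulated enrichment of 1 gene list was the 1 list called among 23, and 30 planted shared entries gave an overlap of 30. The planted hexamer had an odds ratio of 7.78, above the 1.88 of the real windows. These checks therefore cover the code and not its power for effects of the reported size. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9. The IDR scores were not graded, so the planned restriction to the top score was not run.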

Results

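UNC-62, a homeodomain protein of the Meis class, was profiled in L1 larvae, the first larval stage, in 2 biological replicates. The IDR peaks of ce11 had signal values from 35.0 to 128 and a median of 40.6. The strongest peaks lay beside cdc-48.1, which encodes a protein-remodelling ATPase, inside Y111B2A.12, beside the ribosomal protein gene rpl-3, and inside unc-62 itself. Read depth is unknown, and with 1 group no comparison between conditions was possible.

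Among the 20 strongest IDR peaks, that of cdc-48.1 (chromosome II, 10563402 to 10563737) had a signal of 128 and lay 163 bp from the 5′ end. The Y111B2A.12 peak (chromosome III, 12612502 to 12612837) had a signal of 123 and lay in an intron. The peak of rpl-3 (chromosome III, 3867392 to 3867727) reached 99.7, that shared by Y17G9B.5 and rpl-20 reached 86.8, and that of rpl-35 reached 80.2, all in intergenic sequence. Peaks followed whose nearest genes were T23G4.127 (75.5), tasp-1 and K01G5.10 (70.1), tos-1 (68.9), cox-5A (68.3), the histone gene his-37 (68.0), egg-5 (66.6), nhr-88 (64.8), iff-2 and F54C9.14, W02H3.3 (63.7), puf-9 (63.3), and rpl-15 and K11H12.8 (61.5). The summit was 2784 bp from the 5′ end of T23G4.127, 2574 bp from that of nhr-88 and 4017 bp from that of W02H3.3. The others in this list lay within 1 kb. The gene pqn-41 held 4 IDR peaks in introns across 5225 bp of chromosome III, with a highest signal of 72.8. In replicate 1, 2 of these had no entry and the others ranked 12 and 3876, while all 4 ranked 21 or better in replicate 2.

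The first comparison asked whether the strongest sites were shared by the replicates. The peaks of cdc-48.1, Y111B2A.12 and rpl-3 and the stronger unc-62 peak ranked among the first 6 entries of both replicates. At the summit of the weaker unc-62 peak replicate 1 had a separate entry that ranked 8, while both peaks met the same replicate 2 entry. At rpl-3 the signal was 32.0 in replicate 1 and 66.4 in replicate 2, and at his-37 it was 7.44 and 52.4. The median rank of the IDR peaks listed in a replicate was 288.5 in replicate 1 and 64 in replicate 2. The top list of each replicate was as long as the IDR list, and 27 top entries of replicate 1 (22.7%) met a top entry of replicate 2, against a mean of 0.149 in random draws (1-sided permutation p = 0.001, the smallest that 1000 draws can give).

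Of the IDR peaks, 41 (34.5%, interval 26.0 to 43.7%) met a top entry of replicate 1 and 87 (73.1%, interval 64.2 to 80.8%) a top entry of replicate 2. With 595 top entries the share was 52.9% for replicate 1 (interval 43.6 to 62.2%), and for replicate 2 the interval was 92.8 to 99.5%. Signal was weakly related between replicates across 9888 matched entries (Spearman rho 0.12), which are not independent replicates. Across the 112 IDR peaks listed in both replicates rho was -0.012, in a set that had been selected on pooled signal.

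**Figure D1:**
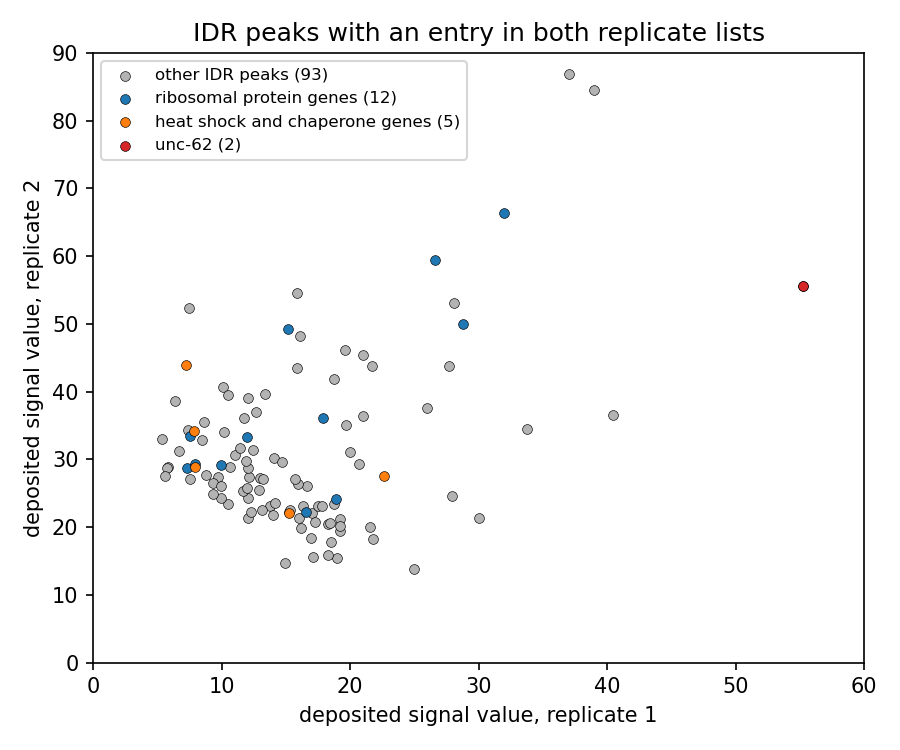
Deposited signal value in replicate 1 (horizontal) and replicate 2 (vertical) for the 112 IDR peaks with an entry in both lists, each point being the strongest overlapping entry. The overlapping unc-62 points lie at 55.2 and 55.6.

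The next comparison asked where the IDR peaks lay. Peaks were concentrated near the 5′ ends of protein-coding genes, and 74 (62.2%, interval 52.8 to 70.9%) lay within 1 kb, against 36.1% of entries below the threshold (odds ratio 2.91, Fisher exact p = 1.36e-08). Relative to protein-coding genes, intergenic sequence held 86 IDR summits, introns 24, 5′ UTRs 6, coding exons 2 and 3′ UTRs 1. Coding exons held 1.68% of IDR summits, against 4770 of the 29865 entries below the threshold (odds ratio 0.0899, Fisher exact adjusted p = 1.43e-06 over 6 features). The X chromosome held 16 IDR peaks (13.4%) against 5371 of the 29865 entries below the threshold, a difference that did not pass (odds ratio 0.708, Fisher exact p = 0.231). In the top list of replicate 1 alone the X odds ratio was 0.511 (Fisher exact p = 0.0227).

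Ribosomal protein genes and chaperone genes were the lists found near IDR summits more often than other genes. Of 73 ribosomal protein genes considered, 13 (17.8%, interval 9.84 to 28.5%) had a 5′ end within 1 kb of an IDR summit, against 0.987% of other genes (odds ratio 21.7, Fisher exact adjusted p = 2.19e-11). They comprised 7 genes of the large subunit, led by rpl-3, rpl-20 and rpl-35, and 6 of the small subunit. The distances ranged from 8 to 739 bp, and the farthest summit lay past the 3′ end of the gene and nearer to another gene. With only the single nearest gene counted, 7 remained (odds ratio 15.3, Fisher exact adjusted p = 2.64e-05), and the top list of replicate 1 alone had 5 (odds ratio 8.76, Fisher exact adjusted p = 0.0100).

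Of 18 heat shock and chaperone genes, 6 (33.3%, interval 13.3 to 59.0%) had such a summit (odds ratio 47.0, Fisher exact adjusted p = 3.16e-07). They were hsp-90 (signal 53.6), the mitochondrial chaperonin gene hsp-60 (51.7), the chaperonin subunit genes cct-1 (39.7) and cct-8 (36.9), hsp-12.3 (39.4) and hsp-1 (39.2). The hsp-12.3 summit lay past the 3′ end of the gene, beside an snRNA gene, in a window with 68.3% unique 31-base words. Without genes reached only past the 3′ end, 5 chaperone genes remained (odds ratio 36.7, Fisher exact adjusted p = 1.21e-05). Several shared the summit with a nearer gene on the other strand, and with only the single nearest gene counted the chaperone odds ratio was 7.82 (Fisher exact adjusted p = 0.587). In the top list of replicate 1 alone the chaperone adjusted p was 0.122 by the Fisher exact test.

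The TALE homeobox, Wnt signalling, insulin signalling and histone lists each had 1 member near an IDR summit. The summit at ceh-20, which encodes the Pbx-class partner of UNC-62, had a signal of 57.9 and lay 682 bp upstream of the 5′ end (chromosome III, 6979034 to 6979369). The TALE homeobox list had 1 of 5 members near a summit (Fisher exact adjusted p = 0.417). It also includes unc-62, which held 2 IDR peaks farther than 1 kb from its 5′ end and so was not counted. The dishevelled gene mig-5, which shared its summit with cct-1, was the 1 of 15 Wnt signalling genes, and the insulin-like peptide gene ins-39 (signal 35.5) the 1 of 25 insulin signalling genes. The histone list had 1 of 17, his-37. None of these 4 lists passed the test within 1 kb, while the histone and insulin signalling lists passed within 2 kb. Neighbouring genes can share a summit, so the 2 kb passes may rest on fewer summits than genes.

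The other 17 lists had 0 members near an IDR summit. These included cuticle collagens (0 of 56, upper bound 6.38%), nuclear hormone receptors (0 of 132, upper bound 2.76%), body wall muscle markers (0 of 17), axon guidance genes (0 of 24), pan-neuronal genes (0 of 11) and the Hox genes (0 of 4). Of all 9799 genes considered, only 109 had such a summit, so 0 is a likely count in all but the largest of these lists, the nuclear hormone receptors. None of the 17 lists differed from other genes (lowest Fisher exact p = 0.408, nuclear hormone receptors). The Hox genes ceh-13 and mab-5, named after their values were seen, had pooled entries of 34.7 and 33.7 that ranked 122 and 135, just below the threshold. In the top list of replicate 2 alone, 1 of 4 Hox genes had a summit (Fisher exact adjusted p = 0.316).

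**Figure D2:**
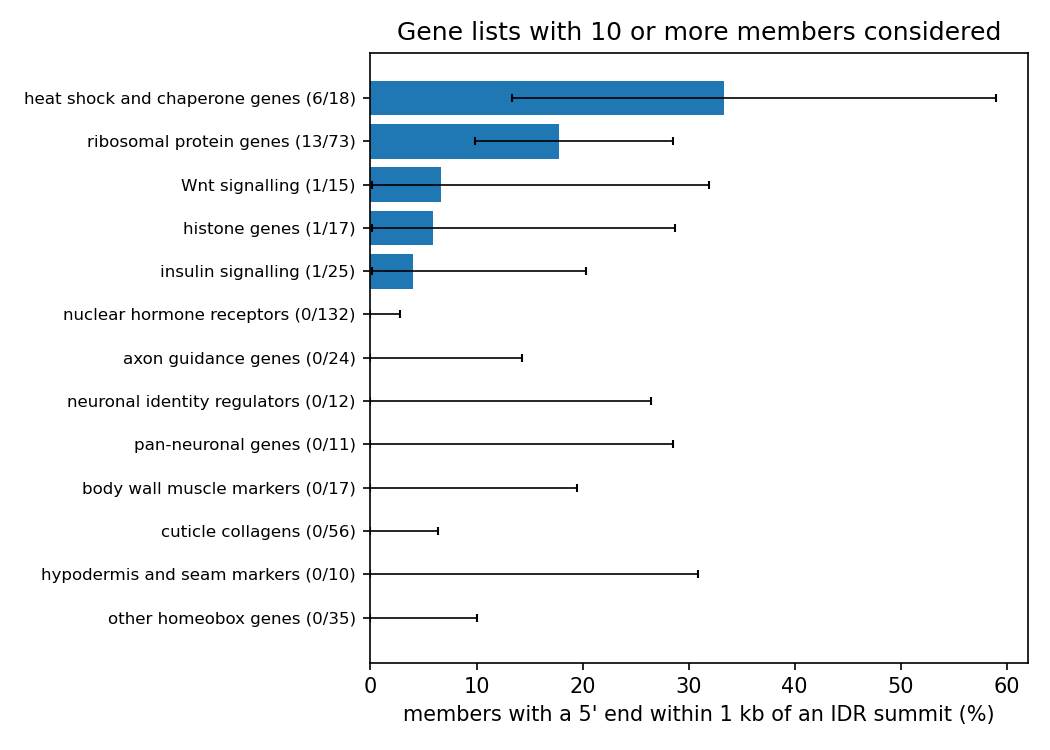
Share of each gene list with a 5′ end within 1 kb of an IDR summit, in percent, for lists with 10 or more genes considered, with exact 95% intervals. Chaperone genes (33.3%) and ribosomal protein genes (17.8%) lie above the remaining lists.

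At the transgene loci, unc-62 carried 2 overlapping IDR peaks and unc-119 carried 0. The unc-62 peaks (chromosome V, 4507927 to 4508262 and 4508126 to 4508461) had signals of 92.2 and 70.2. Both summits lay in sequence annotated as 5′ UTR, 10.6 and 10.8 kb downstream of the gene's 5′ end, and the nearest 5′ end was that of T28F12.1, 4938 and 4739 bp away. A peak of signal 39.2 lay 2.2 kb upstream of unc-62. The 40 kb window centred on unc-62 held 34 pooled entries, against a median of 12 over 2503 windows, and that of unc-119 held 17.

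**Figure D3:**
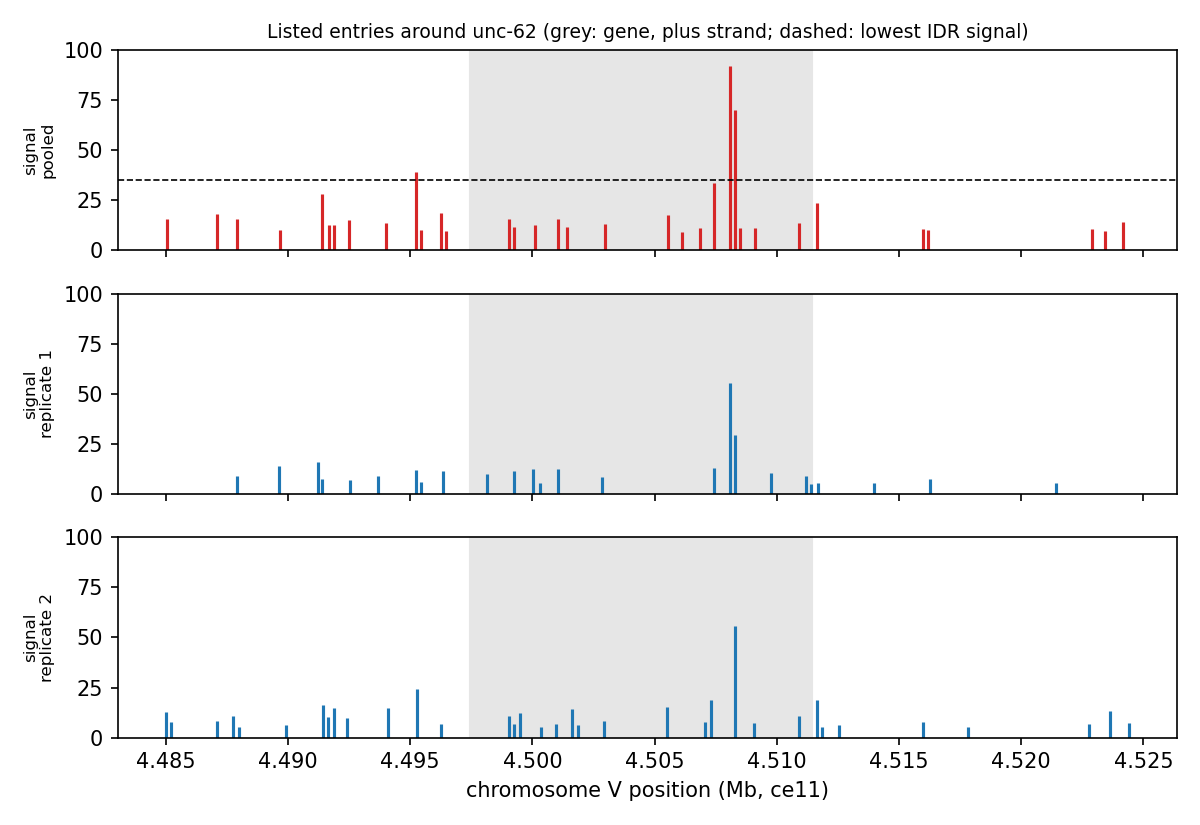
Signal of each listed entry around unc-62 on chromosome V (position in Mb, ce11) in the pooled, replicate 1 and replicate 2 lists. The strongest entries in all 3 lists lie near the downstream end of the gene.

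The Meis hexamer TGACAG was present in 15 IDR windows (12.6%, interval 7.23 to 19.9%) and in 7.14% of 1190 matched windows. The difference did not pass after adjustment (odds ratio 1.88, Fisher exact p = 0.0443, adjusted p = 0.177), and in the top list of replicate 1 alone the share was 6.72% (odds ratio 1.10). The Y111B2A.12 window held the site TCTGTGTTGACAGATCTCTT (chromosome III, 12612698 to 12612717, in an intron), and the mig-5 window held GCCCTAGTGACAGCTGGTGT (chromosome II, 8185178 to 8185197, intergenic). Over all windows together, none of the other 7 motifs passed by the Fisher exact test. The nearest was the GAGA repeat, in 10.9% against 4.45% of windows (odds ratio 2.63, Fisher exact adjusted p = 0.0504). The Hox motif was in 2.52% against 5.13% and the GATA motif in 22.7% against 29.8%.

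A division of the windows by distance to a 5′ end was added after the peak positions were seen. Farther than 1 kb, 10 of 45 IDR windows (22.2%) held the Meis hexamer against 8.22% of matched windows (odds ratio 3.19, Fisher exact adjusted p = 0.0494 over both classes). Within 1 kb the numbers were 5 of 74 (6.76%) against 6.49% (odds ratio 1.04). The shorter Meis core was in 53.3% against 33.3% of the farther windows (odds ratio 2.29, Fisher exact adjusted p = 0.0494). Within 1 kb the GATA motif was less frequent, in 14.9% against 29.1% (odds ratio 0.426, Fisher exact adjusted p = 0.0494). The difference in the hexamer between both classes of IDR peak had a Fisher exact p of 0.0211. None of these 3 motif results passed in the top list of replicate 1 alone, where the odds ratio was 2.83 for the hexamer (Fisher exact adjusted p = 0.107), 1.75 for the core and 0.979 for GATA. In that of replicate 2 alone the core did not pass either (odds ratio 1.55).

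**Figure D4:**
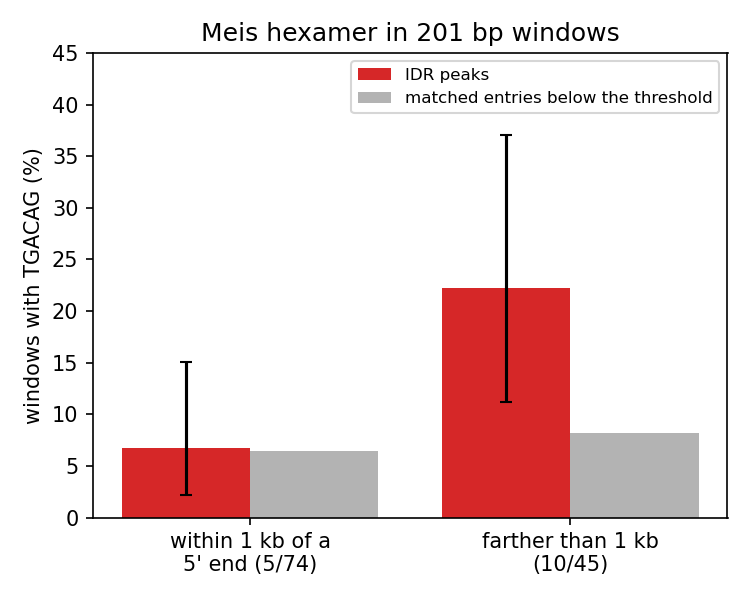
Share of windows reaching 100 bp either side of the summit that held the Meis hexamer, in percent, for IDR peaks (red, exact 95% intervals) and matched entries (grey). The IDR share is 6.76% within 1 kb of a 5′ end and 22.2% farther away.

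The lists of both builds were compared. The IDR list of ce10 held 125 peaks, 6 more than that of ce11, and the X chromosome, with 20 against 16, differed most. Chromosome III held 33 in ce10 and 32 in ce11.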

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

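The −log10 q-value column, which ranked no main comparison, held 54 pooled entries at its highest value outside the IDR list. Their signals lay between 31.4 and 35.0. Of these entries, 32 lay within 1 kb of a gene 5′ end and 16 lay on X.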

How the results depend on the processing

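Of 95 alternatives, 69 left a result's direction and side of the threshold, or its value, as reported, and 0 reversed a called result; 36 were chosen after seeing the data. The promoter odds ratio passed in all 7 of its alternatives (2.03 to 4.61), as did the ribosomal protein odds ratio in all 9 (8.76 to 39.4) by Fisher exact tests. With the 59 IDR peaks above the median signal, a number fixed by construction, the share in the top list was 45.8% for replicate 1 and 94.9% for replicate 2, 1 gene list passed, and the chaperone odds ratio was 22.9 and no longer passed. Among IDR peaks only, the signal rho was -0.012. With 1 replicate left out, odds ratios ranged from 14.4 to 35.4 for chaperones, 0.511 to 0.922 for X, 1.26 to 1.88 for chromosome III, 1.10 to 1.41 for the Meis hexamer, and 1 to 2 gene lists passed. Without replicate 2 the chaperone and chromosome III calls were lost and the X difference passed. With the single nearest gene 1 list passed (chaperone odds ratio 7.82), at 2 kb histone genes and insulin signalling passed too, and without summits past a 3′ end the same 2 lists passed (chaperone odds ratio 36.7). The Meis hexamer passed within 50 bp (2.45), against unmatched entries (2.12) and in peaks farther than 1 kb (3.19), but not within 250 bp or against shuffled sequence. Without replicate 1, without replicate 2 and above the median signal, in that order, odds ratios were 3.20, 2.83 and 4.30 for the hexamer farther than 1 kb, 1.55, 1.75 and 1.86 for the Meis core there, and 0.419, 0.979 and 0.469 for GATA within 1 kb. Of these 9, only the hexamer and GATA without replicate 1 passed. Translation factors passed without replicate 1 (15.2) but not without replicate 2 (4.22), while small RNA genes passed in all 4 alternatives (4.98 to 8.18). Chromosome III no longer passed with 1 peak per 10 kb (1.68). Above the median signal the builds differed by at most 2 peaks per chromosome, against 4. The cause was not tested. The interval midpoint equals the summit, so that alternative was void. The ranking by q with ties broken by signal gave the reported overlap, but it was close to the ranking by signal. At the highest −log10 q-value, 86 replicate 1 entries and 283 replicate 2 entries were tied, so signal ordered them again. Unknown depth limits any comparison of replicate strength.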

Other observations

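The tests of translation factors, small RNA genes and chromosome III, the final test of replicate strength, and the control condition of the hexamer test, were chosen after the results were seen. Translation factor genes had 4 of 28 members near an IDR summit (eef-1A.1, eef-2, eif-3.C and iff-2; odds ratio 15.3, Fisher exact p = 0.000241), and the top list of replicate 1 alone had 1 (odds ratio 4.22, Fisher exact p = 0.219). Small RNA genes (tRNA, snRNA or snoRNA) lay within 300 bp of 10 IDR summits (8.40%) against 1.23% of entries below the threshold (odds ratio 7.35, Fisher exact p = 2.83e-06), and 5 of the 10 were snRNA genes, among them sls-2.4 and sls-2.2. All 6 IDR windows with under 100% unique 31-base words were among these 10, with all 5 at snRNA genes and a lowest share of 63.7%, so repeated sequence stays open there. The 10 included the summits of rps-12 and rps-26, named after their values were seen, and of hsp-12.3. The small RNA count therefore overlaps those of the ribosomal protein and chaperone lists. Chromosome III held 32 IDR peaks (26.9% against 15.2%, odds ratio 2.05, Fisher exact adjusted p = 0.00713 over 6 chromosomes). With 1 peak kept per 10 kb its odds ratio was 1.68 (Fisher exact adjusted p = 0.183), with 108 peaks left, and without replicate 2 it was 1.26 (Fisher exact adjusted p = 0.616). Ranking all 2080 hexamers by Fisher exact p as a description, 67 passed adjustment and GACGCA led (log2 odds 2.08), followed by GCGCGA (log2 odds 2.45), while TGACAG ranked 312 by p and 173 by odds ratio. Parts of the GAGA repeat, GAGAGA and AGAGAG, passed in this ranking (log2 odds 1.45 and 1.48, Fisher exact adjusted p = 0.000212).

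IDR summits within 1 kb of a 5′ end included those of 13 ribosomal protein genes. Reads shared between gene copies are argued against, since the share of 31-base words found once in the genome was 100% in each of these windows. The list passed in the top list of each replicate, and the lower odds ratio was 8.76, in replicate 1 (Fisher exact p = 0.000435). This argues against a single replicate as the only source of the list's enrichment. Replicate 1 alone had 5 members and replicate 2 alone had 14, so the members rest more on replicate 2. The weakest of the 13 summits in replicate 1 ranked 13604 there, with a signal of 7.30 against a list median of 7.05. The Meis hexamer had an odds ratio of 1.04 in IDR windows within 1 kb of a 5′ end against matched entries (Fisher exact p = 0.808), and was in 0 of 13 ribosomal protein windows, which allows up to 24.7%. Recovery of gene 5′ ends without UNC-62 and binding without this hexamer cannot be told apart, because no control list was analysed here.

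For the peaks in unc-62, repeated sequence is argued against, since the lowest share of unique 31-base words was 100%. Extra copies of the transgene may raise signal over the locus, and the number of entries around unc-62 exceeded that of 99.96% of windows. The median signal of entries below the threshold was 13.2 there and 11.2 around unc-119, against 11.9 genome-wide, in lists that hold only entries above a floor. The window of unc-119, also on the transgene, exceeded 83.8% of windows, short of the bound set for copies. That gene spans 6295 bp of its 40 kb window, and the rest may lie outside the transgene, so this count cannot decide. Extra copies and binding of UNC-62 to its own gene cannot be told apart, because no strain without the transgene was analysed here.

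Replicate 2 contributed more of the IDR peaks. Repeated sequence is argued against for most strong replicate 1 entries. Only 1 of the 92 that met no top replicate 2 entry had mostly non-unique words. Among 1991 entries sampled below the threshold 8 did, and the median was 100% unique words in both sets. Weaker enrichment of the same sites in replicate 1 was tested in 2 versions: the IDR peaks had a median rank of 486 in replicate 1 with the 7 unlisted peaks ranked last, a test set aside because pooled signal had selected them, and the top replicate 2 entries then had a median rank of 2914 there, close to the bound of 3000. The top replicate 1 entries ranked 2695 in replicate 2, a similar value, the median signal of all entries was 7.05 in replicate 1 and 7.22 in replicate 2 (highest 55.2 and 86.9), and with depth unknown this explanation stays open. Other strong sites in replicate 1 also stay open, with 72.3% of its top entries meeting any replicate 2 entry against 84.9% the other way, and no biological explanation was tested.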
